A study of Rattus norvegicus with 9 samples.

How the data were processed

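Total RNA was prepared with Tri-Reagent from the left ventricle of individual rats, pooled, labelled with a radioactive nucleotide and hybridised to a Clontech array, per the labels' protocols. The design text counts 27 libraries, which is 3 pools in each of 9 groups, and GEO holds 1 sample per group. The number of arrays limits the precision.

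The deposited series table holds log2 values, which per the labels are normalized ratios of geometric means, treatment over control. How they were normalized, the scanner software, any background correction and the choice of the 87 rows are not given in the sources used here. A second deposited table gives intensity values on a linear scale for the same 87 rows. These go below 0 in 4 groups and are empty in 11 rows of the heat-stressed group. Whether a column of the intensity table is a pool or a summary of pools, and whether it was scaled, is not given in the sources used here. The log2 table was the main source, because the design text states what it holds. Both tables agree in direction only in part: the correlation across rows between the listed ratio and the ratio of intensities was between 0.229 (heat-stressed) and 0.762 (reacclimated, heat-stressed). In 6 of the 8 treated groups the group's own intensity column gave the highest correlation. The exceptions were the heat-stressed group, whose ratios correlated best with the intensities of the 2 d acclimated, heat-stressed group (0.489), and the deacclimated group, with those of the reacclimated, heat-stressed group (0.556). For comparisons without the control, the correlation between both tables was between 0.407 (deacclimated against 1 mo acclimated) and 0.829 (1 mo acclimated, heat-stressed against unstressed).

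Some values of the log2 table were read as a floor. The control column, a ratio of the control to itself, was 0 (within 1e-05) in 78 rows. It was -3.32 in 8 rows and -6.64 in 1 row. These equal log2 of 0.001 divided by the number of pools, taken once or 2 times. That they come from pools set to a floor is a reading, which the sources used here do not state. By intensity the control stood at 6250 in R724, above its median of 3318, and between 66.8 (R105) and 1566 (A042) in the others. In the heat-stressed group 6 values between -4.06 and -2.87 lay apart from the next lowest at -1.29, a gap of 1.58, as did 1 value of the 2 d acclimated group. Values were taken as lying apart if below -2.5 with a gap of at least 0.9 above them. In the alternatives below, values at the floor are the control values away from 0 and the values lying apart, on that reading. For all comparisons the control was taken as 0.

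Differences were computed per row between log2 ratios, so that the control cancels wherever it is not a group of the comparison. With 1 value per group no test was run between 2 groups, and rows at least 2-fold (log2 of 1) higher or lower were counted in 16 comparisons. The effect of heat stress common to the 4 states (not acclimated, 2 d acclimated, 1 mo acclimated and reacclimated) was tested with limma (lmFit and eBayes) on the 4 differences per row between a stressed and its own unstressed sample, with 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The spread there is between states, so it holds any difference in response between states as well as error. This test was added after the data were seen. On simulated data with 20 of 87 rows shifted by 2 log2 units and an error of 0.3 log2 units (SD) per group, it called 100% of the shifted rows, and 3.61% of its calls were false. That error was assumed, was equal for all rows and held no difference in response between states. In the real data the SE went from 0.21 (R602) to 0.69 (A061), so these shares do not carry over to them. Root mean square differences, Pearson's r and Spearman's rho over rows were given 95% intervals from 10000 resamples of rows. For groups compared with the same control, 10000 simulations drew unchanged groups with a common control error whose variance was taken as 50.0% of the smaller of both groups' variances over rows. The counting step was tested on simulated data of 87 rows: with 20 rows shifted by 2 log2 units and an error of 0.3 log2 units (SD) per group, 99.0% of the shifted rows and 1.78% of the other rows reached 2-fold over 200 draws. That error was assumed, as 1 value per group gives no estimate of it. These shares check the counting and are not error rates of the counts below. Intensities were used on the log2 scale, where above 0, centred on each sample's median over the 59 rows above 0 in all samples. Counts by intensity therefore cover only rows above 0 in both groups, between 66 and 87 rows per comparison. R 4.3.3 with limma 3.58.1, and Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

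The groups, comparisons, alternatives and a rule for named rows were fixed before the data were examined. That rule took the 10 largest differences in each direction per comparison. As the files do not pair row names with genes, and 0 of 87 names were found in the RefSeq gene table of assembly GRCr8, it was limited to the first 2 of them in each direction per comparison. Rows named for other reasons were chosen after their values were seen. The 19 gene lists fixed beforehand, among them heat shock proteins, contraction and calcium handling, and markers of other cell types, could not be applied without gene names, and no list result is given.

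Alternatives were centring each sample on its median, a threshold of 1.5-fold, the intensity table, leaving out the 25% of rows with the lowest mean intensity (22 rows), median absolute differences, Spearman's rho, and leaving out the 5% of rows with the largest spread (5 rows). Leaving out values at the floor or lying apart, leaving out each state from the common heat stress test, centring before the overlap of groups was counted, and subtracting the control column as listed were each added after seeing the data. The processing can affect the measurements in these ways: a ratio with a pool at the floor overstates a difference, a change in scale moves all rows of a group together, and background subtraction leaves dim rows near or below 0.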

Results

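Gene expression was measured in the left ventricle of the rat heart after exposure to heat, after loss of the acclimated state and after its re-induction. Heat acclimation is the slow adjustment of an animal to a warm environment, here 34 °C for 2 days (short term) or 1 month (long term). Heat stress was an acute exposure to 41 °C for 2 h followed by 1 h of recovery at 24 °C. Deacclimated rats spent 1 month at 24 °C after 1 month of acclimation, and reacclimated rats were then returned to 34 °C for 2 days. The 9 groups were untreated control, heat-stressed, 2 d acclimated, 1 mo acclimated, deacclimated and reacclimated rats, and the 2 d acclimated, 1 mo acclimated and reacclimated rats after heat stress.

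Each group was represented by 1 sample, deposited as 1 value per array row, which per the labels summarised 3 pools of RNA, with 6 animals stated. There were therefore no replicates within a group, and the differences between 2 groups below are sizes without a p-value. Only the effect of heat stress common to 4 states of the rats was tested, over its 4 pairs of a stressed and an unstressed sample. The tables held 87 array rows, and none of the 87 row names was paired with a gene in the files or in the reference table, so rows are given by their array names. A row with an intensity below 0 in the second table was read as not above background, which the sources used here do not state. The size of its listed difference is then uncertain. Values are log2 ratios to the control, and a difference of at least 2-fold is a log2 difference of at least 1.00. The number of arrays limits the precision. Median intensities in the second deposited table lay between 1064 (2 d acclimated, heat-stressed) and 4962 (2 d acclimated), against 3318 in the control.

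The median log2 ratio of the 87 rows was -0.06 in heat-stressed rats, 0.23 after 2 d acclimation, 0.13 after 1 mo acclimation, 0.19 after deacclimation and 0.41 after reacclimation. With heat stress on top it was -0.26 after 2 d acclimation, 0.01 after 1 mo acclimation and 0.30 after reacclimation. Counts after centring each group on its own median are therefore given beside the main counts where the balance of higher and lower rows moved.

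**Figure D1:**
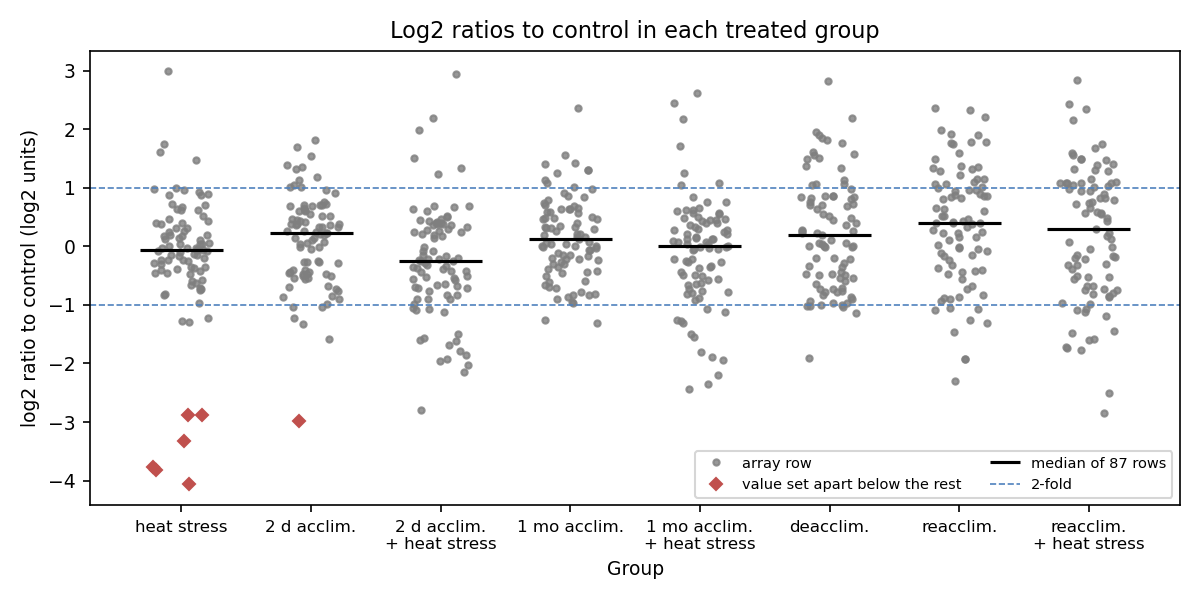
Log2 ratio to control (vertical axis, log2 units) of the 87 array rows in each of the 8 treated groups (horizontal axis). Grey points are rows, black lines are medians of 87 rows, dashed lines mark 2-fold, and red diamonds are the 6 values of the heat-stressed group and the 1 value of the 2 d acclimated group that lay apart below the rest; points are spread sideways at random for legibility.

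The first comparison asked what acute heat stress did in rats that had not been acclimated. Row R609 was 7.93-fold higher than in the control (log2 difference 2.99), and its intensity was 27376 against 1282. The control value of R609 was itself listed at -3.32, where a ratio of the control to itself should be 0. With that value subtracted the log2 difference was 6.31. Row 755R was 3.34-fold higher, although its scaled intensity was lower than in the control (log2 difference -1.32). The rows listed furthest below the control were R198 (-4.06), with the opposite sign in scaled intensity (0.74), and R590 (-3.82, with -1.03 in scaled intensity). Both values lay apart below the rest of the group. In all, 5 rows were higher and 9 were lower by at least 2-fold. Of these 14 rows, 7 held such a control value (R609) or a value that lay apart below the rest of the heat-stressed group (6 rows), and 7 rows (4 higher and 3 lower) were left without them. The second table gave 16 rows higher and 7 lower, over the 76 rows with an intensity in both groups. The lowest intensity in the heat-stressed group was 1511, which limits the falls it can show.

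Short-term acclimation was then set against the control. Row R058 was 3.53-fold higher (1.82, with 0.71 in scaled log2 intensity) and row A046 was 3.25-fold higher (1.70), with an intensity of 45957 for A046 against 3972. Row A061 was listed lowest (-2.97), at a value apart from the rest of its column and an intensity below 0. The control value of A061 was listed at -3.32, and with it subtracted A061 was above the control (0.35). Row R364 followed (-1.59, with -0.31 in scaled intensity). In total 11 rows were higher and 6 lower by at least 2-fold, and after centring 6 were higher and 10 lower. By intensity, 16 rows were higher and 24 lower.

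After 1 month of acclimation, row R332 was 5.12-fold higher than in the control (2.36), with an intensity of 905.0 against 184.1. Row 635R was 2.94-fold higher (1.56), with the opposite sign in scaled intensity (-1.13). Rows R470 (-1.32) and R056 (-1.26) were the only rows lower by at least 2-fold, against 10 higher rows, and after centring the counts were 8 higher and 5 lower. The second table gave 15 higher and 25 lower. Set directly against 2 d acclimation, which uses no control value, 5 rows were higher and 1 was lower after 1 month. These included A061 (3.46), whose value after 2 d acclimation lay apart, R332 (1.75, intensity below 0 after 2 d acclimation) and the lower row 849R (-1.04, or -0.94 after centring, when 5 rows were higher and 0 lower). Without the 25% of rows with the lowest intensities, 1 row differed.

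**Figure D2:**
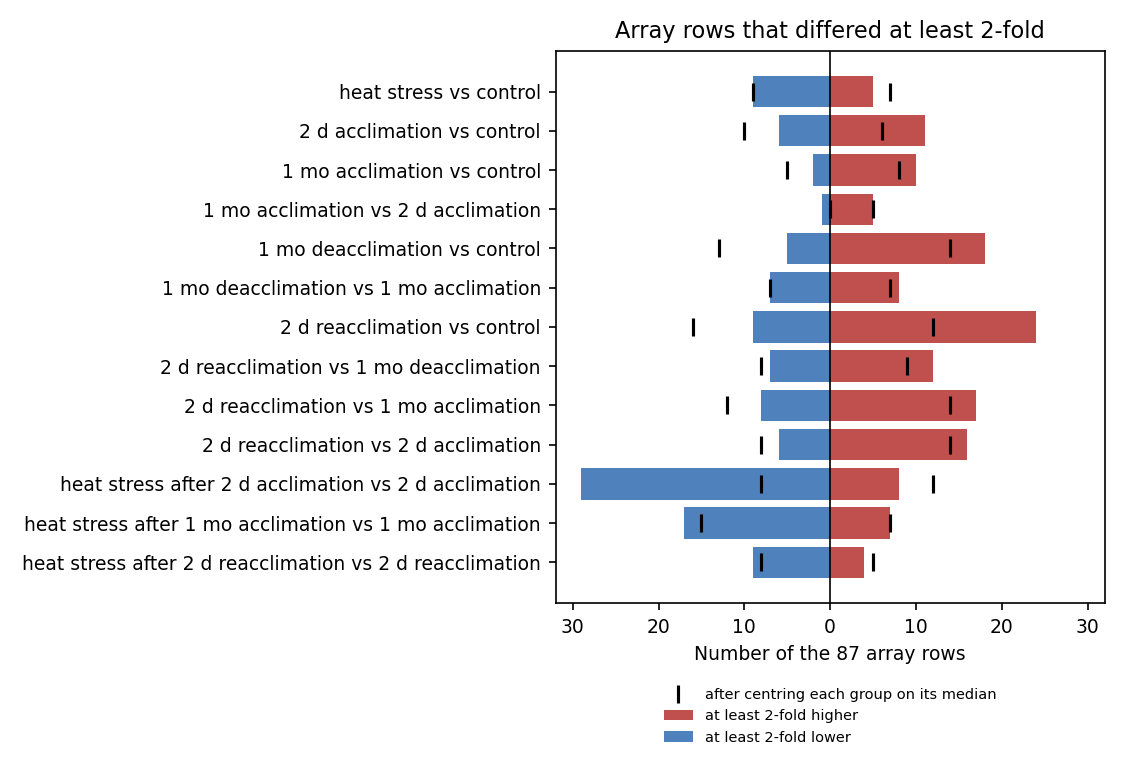
Number of the 87 array rows (horizontal axis) at least 2-fold higher (red, to the right) or lower (blue, to the left) in 13 comparisons (vertical axis); black ticks give the same counts after each group was centred on its median. Heat stress after 2 d acclimation gave 29 lower and 8 higher rows, and 8 lower and 12 higher after centring.

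The deacclimated group addressed what was left after the rats had lived at 24 °C for 1 month. Row R570 was 7.04-fold above the control (2.82) and row A022 was 4.59-fold above it (2.20). Their intensities were 7863 against 2632 for R570 and 11763 against 1458 for A022. After scaling, the difference of R570 by intensity was 0.91 in log2 units, below 2-fold. The control value of A022 was listed at -3.32, as for R609, and with it subtracted the difference of A022 was 5.52. Rows R724 (-1.91, also with a control value listed at -3.32, and with an intensity below 0) and A018 (-1.14) were listed furthest below. With the listed control value subtracted, R724 was above the control (1.41). In all 18 rows were higher and 5 lower, or 14 and 13 after centring. By scaled intensity the counts were 18 higher and 27 lower. Against the 1 mo acclimated group, the stage that preceded deacclimation in the protocol, 8 rows were higher and 7 lower, led by A022 (5.67-fold) and R570 (4.54-fold, with 0.66 in scaled log2 intensity) upward and by R724 (5.67-fold) and A059 (3.17-fold) downward, both with intensities below 0 after deacclimation. Without the 25% of rows with the lowest intensities, 7 were higher and 1 lower.

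Reacclimation for 2 days gave 24 rows higher and 9 lower than in the control, or 12 and 16 after centring. Row R570 was 5.12-fold higher (2.36, with 0.72 in scaled log2 intensity) and row R208 5.04-fold higher (2.33), the latter with a scaled intensity slightly below the control (-0.37). Rows R637 (-2.31) and R045 (-1.93) were lowest, with intensities of 742.2 against 5202 and 535.8 against 5837. Scaled intensities gave 18 higher and 26 lower rows.

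Return to the heat was also compared with the deacclimated state it followed. There, 12 rows were higher and 7 lower, or 9 and 8 after centring. Row A017 was 5.76-fold higher (2.53), with an intensity of 4761 against 652.6, and row A018 was 4.43-fold higher (2.15, with 0.88 in scaled intensity). Rows R523 (-1.56) and S62R (-1.31) were lower. Without the 25% of rows with the lowest intensities 7 rows differed, and the second table gave 4 higher and 17 lower.

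The reacclimated group was next compared with both first-time acclimations. Against 1 mo acclimation, 17 rows were higher and 8 lower, or 14 and 12 after centring. Row A022 was 5.68-fold higher (2.51) and row R516 was 4.88-fold higher (2.29), while R637 (-1.47) and R724 (-1.45, intensity below 0 after reacclimation) were lower. The 2 d acclimated group had the same latest heat exposure, 2 days, but not the earlier month at 34 °C and month at 24 °C. Against 2 d acclimation, 16 rows were higher and 6 lower, or 14 and 8 after centring. Row A022 was again highest (2.75, intensity 13606 against 1606), followed by A061 (2.65, a row whose value after 2 d acclimation lay apart and whose intensities were below 0 in both groups). Rows listed lowest were 849R (-1.70, intensity below 0 after reacclimation) and R635 (-1.53). The second table gave 15 higher and 18 lower against 1 mo acclimation, and 16 higher and 22 lower against 2 d acclimation.

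The distance between profiles was taken as the root mean square of the log2 differences over the 87 rows, with 95% intervals from resampling rows, which cover the spread over rows and not that between animals. The reacclimated profile lay 0.79 (0.65 to 0.94) from the deacclimated, 0.93 (0.79 to 1.06) from the 1 mo acclimated, 0.97 (0.82 to 1.12) from the 2 d acclimated and 1.08 (0.95 to 1.21) from the control profile. It was nearer to the deacclimated profile than to the control by 0.29 (0.11 to 0.48). The intervals of its other differences included 0, at 0.14 (-0.02 to 0.30) relative to the 1 mo acclimated and 0.17 (-0.01 to 0.37) relative to the 2 d acclimated profile. The 2 acclimated profiles lay 0.66 (0.48 to 0.87) apart.

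**Figure D3:**
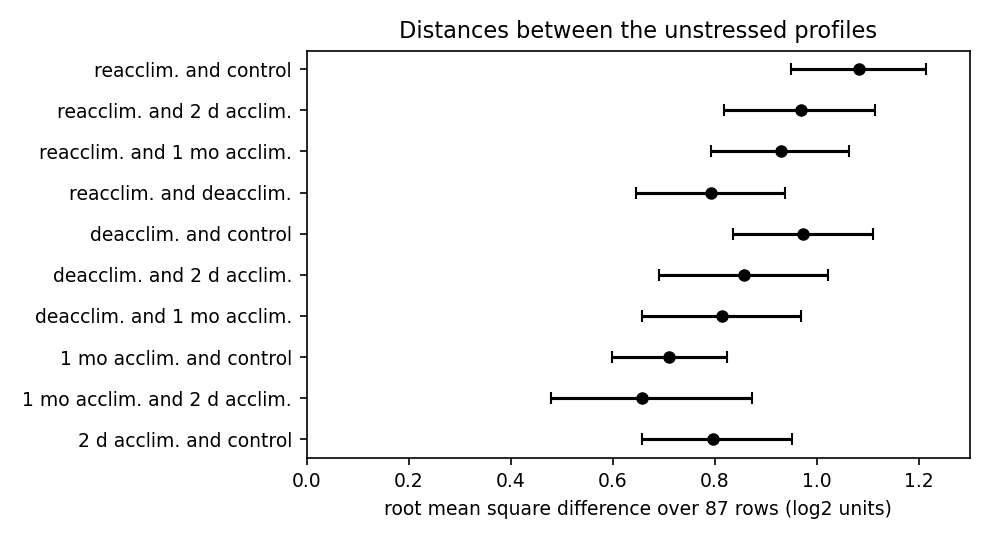
Root mean square difference (horizontal axis, log2 units) between pairs of the 5 unstressed profiles (vertical axis), with bars for 95% intervals over resampled rows. The reacclimated profile lay 0.79 from the deacclimated profile and 1.08 from the control.

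Lists of rows set against the same control share its error, so their overlap was compared with chance. The deacclimated and reacclimated groups shared 13 higher rows, where independent lists would share 4.97 and simulated unchanged groups with a common control shared 4.99 on average, with an upper limit of 10 (the upper end of the 95% range). The correlation across rows was r = 0.685 against a simulated 0.462, and the covariance was 0.667 against 0.453. The 2 d and 1 mo acclimated groups shared 6 higher rows, against 1.26 for independent lists and 2.11 in the simulation (upper limit 5), with a covariance of 0.342 against 0.243. For 1 mo acclimation and reacclimation the overlap was 8 rows, against 2.76 and 2.38 (upper limit 6), with a covariance of 0.354 against 0.243. For 2 d acclimation and reacclimation it was 6 rows, against 3.03 and 3.38 (upper limit 7), with a covariance of 0.401 against 0.315. For 1 mo acclimation and deacclimation it was 6 rows, against 2.07 and 2.31 (upper limit 6), with a covariance of 0.362 against 0.243. The simulated groups have a median near 0, while the real ones lay above it, which adds to the higher and takes from the lower overlaps. After centring, an alternative added after the data were seen, the deacclimated and reacclimated groups shared 9 higher and 8 lower rows, against 1.93 and 2.39 for independent lists. The 2 d and 1 mo acclimated groups then shared 4 higher and 4 lower rows, against 0.552 and 0.575, and 1 mo acclimation and reacclimation 4 higher and 3 lower, against 1.10 and 0.920. For reacclimation with 2 d acclimation the centred overlap was 2 higher and 6 lower rows, against 0.828 and 1.84, and for deacclimation with 1 mo acclimation it was 5 higher and 0 lower, against 1.29 and 0.747. None of the 5 centred overlaps of higher rows exceeded its simulated upper limit. Without centring, the lower overlaps in the order of the higher ones above were 2, 0, 2, 3 and 0 rows. Each was below its simulated mean (5.02, 2.07, 2.40, 3.35 and 2.31), and independent lists would share 0.517, 0.138, 0.207, 0.621 and 0.115 rows. The simulated values and upper limits rest on an assumed error in the control, set for each pair on its own although the control is the same. With 1 control sample that error could not be estimated. The simulation therefore leaves open how much of each excess comes from the shared control, up to all of it.

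Heat stress was then examined in rats with different histories, each against its own unstressed group. After 2 d acclimation, R609 was 6.96-fold higher on heat stress (2.80), and A061 was higher by 3.30 from a value that lay apart, with intensities below 0 in both groups. Rows R040 (-2.52) and R242 (-2.26, intensity below 0 after heat stress) were listed furthest below, and R040 was lower by scaled intensity too (-1.58). There were 8 higher and 29 lower rows. The median difference of all rows was -0.39, and after centring 12 were higher and 8 lower. The second table gave 12 higher and 21 lower, over the 66 rows above 0 in both groups.

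In rats acclimated for 1 month, heat stress left A044 5.04-fold higher (2.33, intensity 10223 against 1959) and A022 4.03-fold higher (2.01). Row A014 was 8.63-fold lower (-3.11) and row A070 6.61-fold lower (-2.72). In all 7 rows were higher and 17 lower, and after centring 7 were higher and 15 lower. The second table gave 18 higher and 17 lower. In reacclimated rats 4 rows were higher and 9 lower on heat stress, led by A044 (2.19) and R609 (2.08) upward and by R590 (-2.26, with 0.35 in scaled intensity) and A017 (-2.07) downward. Without the 25% of rows with the lowest intensities 4 were higher and 3 lower, and the second table gave 14 higher and 8 lower.

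Against the untreated control, the stressed groups showed 6 rows higher and 16 lower after 2 d acclimation, 7 and 13 after 1 mo acclimation, and 26 and 13 after reacclimation. Centring turned the last count to 14 higher and 22 lower, and the second table gave 17 and 34. With the control column subtracted as listed, the counts were 14 higher and 15 lower after 2 d acclimation and 14 and 11 after 1 mo acclimation. R609 was higher after 2 d acclimation (2.94) and 1 mo acclimation (2.62), R332 after 1 mo acclimation (2.44), and R570 after reacclimation (2.42, with 0.74 in scaled log2 intensity). The control value of R609 was listed at -3.32. With it subtracted, R609 was higher by 6.26 after 2 d acclimation and by 5.94 after 1 mo acclimation. Row 755R was 4.60-fold higher after 2 d acclimation and 7.20-fold higher after reacclimation, but its scaled intensity differed from the control by 0.01 and -0.46. Rows listed lowest were R240 (-2.79, intensity below 0) and R045 (-2.14, with -0.04 in scaled intensity) after 2 d acclimation, R242 (-2.44) and R437 (-2.36, with -0.66 in scaled intensity) after 1 mo acclimation, and R011 (-2.84) and R637 (-2.51) after reacclimation.

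The effect of heat stress common to the 4 states was tested with limma on the 4 differences per row (Benjamini-Hochberg over 87 rows), a test chosen after the data were seen. Row R609 was higher by 2.41 ± 0.29 (SE, 4 of 4 states, limma adjusted p = 0.0141) and row A044 by 1.78 ± 0.31 (4 of 4 states, limma adjusted p = 0.0496). No other row passed at 0.05, among them R040 at -1.63 ± 0.35 (limma adjusted p = 0.103), and 17 rows had an unadjusted p under 0.05. By scaled intensity 0 rows passed (R609 at 3.01 ± 0.59, limma adjusted p = 0.112), with 6 at an unadjusted p under 0.05. Leaving out 2 d acclimation or reacclimation also left 0 rows (limma adjusted p of R609 0.117 and 0.0539), leaving out 1 mo acclimation left 1, and leaving out the rats that were not acclimated gave 4 (2 higher and 2 lower).

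State by state, R609 was at least 2-fold higher on heat stress in all 4. It was higher by 2.99 without acclimation (control taken as 0, or 6.31 with the listed -3.32 subtracted). The other differences of R609 were 2.80 after 2 d acclimation, 1.76 after 1 mo acclimation and 2.08 after reacclimation. A044 reached 2-fold in 3 states (1.73, 2.33 and 2.19) and not in rats that were not acclimated (0.89). With values at the floor left out row by row, R609 was higher by 2.21 ± 0.33 over its 3 other states (limma adjusted p = 0.0243). Of the 5 rows at least 2-fold lower in 3 states, R040 showed -0.59 without acclimation, -2.52 after 2 d acclimation, -1.50 after 1 mo acclimation and -1.90 after reacclimation. Leaving out values that lay apart or rested on a control value away from 0, 2 of these 5 rows reached 2-fold in 3 states. No row was lower by at least 2-fold in all 4 states, and 34 rows differed by 2-fold in no state. Over the 6 pairs of states, which share no sample, the responses correlated across rows, which are not independent replicates, most for 2 d and 1 mo acclimation (r = 0.538, interval 0.325 to 0.712, rho = 0.486) and least for 1 mo acclimation and no acclimation (r = 0.0555, -0.163 to 0.271, rho = 0.0541). For no acclimation with 2 d acclimation r was 0.302 (0.0965 to 0.485, rho = 0.199), and for 2 d acclimation with reacclimation it was 0.364 (0.115 to 0.558, rho = 0.213). The first of these was 0.127 without values at the floor or lying apart, and 0.131 without the rows of largest spread. The intervals included 0 for no acclimation with reacclimation (r = 0.281, -0.0562 to 0.556, rho = 0.0956) and for 1 mo acclimation with reacclimation (r = 0.242, -0.0232 to 0.473, rho = 0.133).

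**Figure D4:**
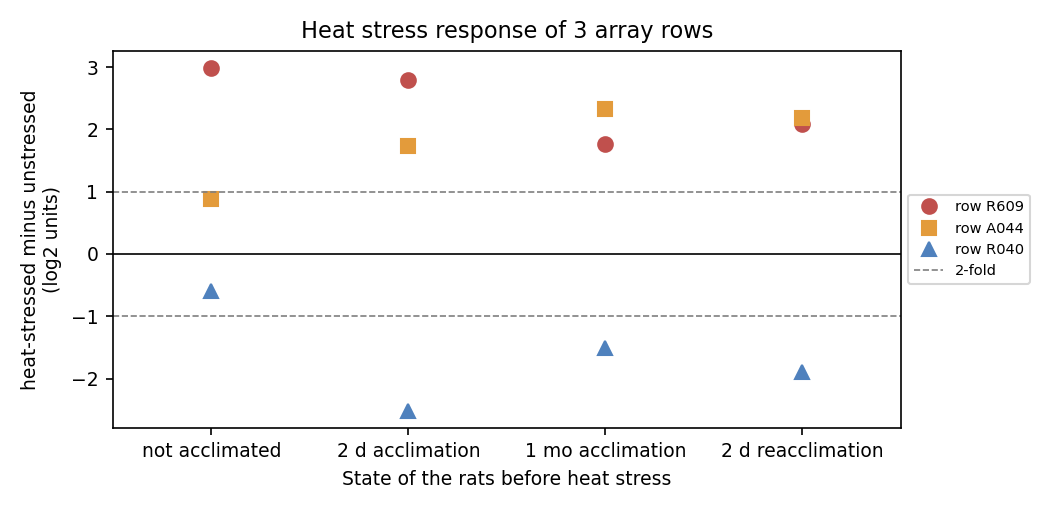
Heat-stressed minus unstressed log2 value (vertical axis, log2 units) of array rows R609, A044 and R040 in rats of 4 states (horizontal axis); each point is a difference of 2 samples without an error, and dashed lines mark 2-fold. R609 lies between 1.76 and 2.99, and R040 between -2.52 and -0.59.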

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

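Of the tests in this part, those on the low heat-stress values, on the shared control, on age and batch, on the scaling factors, on dim rows after 1 mo acclimation and on the common heat stress effect were chosen only after the result was seen. With 1 sample per group, an outlying sample cannot be told apart from its group. The heat-stressed and deacclimated ratios correlated better with another group's intensities (0.489 and 0.556) than with their own (0.229 and 0.466). The cause of this was not tested, and it limits the patterns below that use these 2 groups.

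On heat stress 3 rows were at least 2-fold higher in some states and at least 2-fold lower in others. R635 was at -1.63 after 2 d acclimation and at 1.13 after reacclimation. R087 was at -1.29 without acclimation, at 1.40 after 2 d acclimation and at 1.60 after 1 mo acclimation. R520 was at -1.21 without acclimation and at 1.01 after 1 mo acclimation. These differences were not tested, since each value comes from 1 sample per group, and the rows were chosen after their values were seen.

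The test of a heat stress effect common to the 4 states called 2 rows. Turning the sign of some of the 4 pairs gives 8 splits, too few for a share under 0.05: 1 of them, the real split, called as many as 2 rows, and the highest other called 0.

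The heat-stressed group without acclimation held 6 values far below the rest. If 1 of the 3 pools had been set to the floor, adding its share back would return the values to the range of the other rows, and this held for 6 of 6 (-0.74 to 0.45). The range of the other rows is wide, so this test was lenient, and a pool at the floor is a candidate explanation only. A true fall in all pools stays open. The lowest intensity of this group is 1511, so 0 of the 6 rows could have shown a fall of the listed size there. The 5 rows with an intensity stood above that lowest value, between 2198.8 (R198) and 2623.5 (A017). Their scaled intensities differed from the control by between -1.03 and 1.11. As a fall of the listed size could not have shown by intensity, these values do not decide the question.

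In the groups with an acclimation history (deacclimated, reacclimated, and reacclimated with heat stress), 15 rows were at least 2-fold from the control in all 3 groups, 13 higher and 2 lower (R637 and R011). The median of the 13 was 1.61, 1.78 and 1.32 in these groups, against 0.60 and 0.63 after 2 d and 1 mo acclimation and 0.19 after heat stress alone, but the rows were selected for the first values, and 8 of the 13 reached 2-fold in neither acclimated group. An error in the control shared by all ratios was weighed over all 87 rows. The reacclimated minus the 2 d acclimated profile correlated with the deacclimated ratio (r = 0.295, 0.0460 to 0.509), as did the same difference in stressed rats (0.479, 0.283 to 0.652). Neither difference uses the control or the deacclimated group. Over all rows this argues against control error as the whole source of the deacclimated ratios. The 15 rows were not tested on their own, so control error stays open as their cause. Scaling of the 3 groups cannot be told apart, as 8 of the 15 stayed 2-fold after centring, with an interval of 4 to 13. A step between the intensities and the ratio table stays open too (10 of 15 had the listed direction in all 3 groups by intensity), as do age, rearing period or array batch, for which 0 label fields give a value, and the acclimation history itself, a biological explanation that may account for the pattern but could not be tested on its own.

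Heat stress after acclimation gave more lower than higher rows. After 1 mo acclimation a scaling factor for the group was argued against as the whole cause, since 15 of the 17 lower rows stayed 2-fold lower after centring in the ratio table, although the excess itself is absent by intensity (18 higher, 17 lower) and smaller without the 25% of rows with the lowest intensities (5 higher, 8 lower). After 2 d acclimation 8 of the 29 did, and a scaling factor cannot be told apart there from a fall shared by most rows, since centring removes both. By intensity, also centred, the excess of lower rows stayed (12 higher, 21 lower, over 66 rows above 0 in both groups), so the 2 deposited tables differ on this. Weak signal on dim rows was weighed by Spearman's rho between the difference and the mean intensity in the other groups. After 2 d acclimation rho was -0.0365 (-0.247 to 0.179), under the limit of 0.1 set beforehand, though its interval reached above it. Without the 25% of rows with the lowest intensities, 6 rows were higher and 22 lower. The excess was thus not confined to rows of low mean intensity. Neither check covers weak signal in the stressed group itself, whose median intensity was 1064 against 4962 in its unstressed group. Weak signal therefore stays open there. After 1 mo acclimation rho was 0.0459 (-0.175 to 0.260), also under 0.1 with an interval reaching above it, and dim rows stay open. Heat stress itself may be the source, untested.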

How the results depend on the processing

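The results on the groups with an acclimation history, the common heat stress test with all its alternatives, and the settings without values at the floor (or lying apart) and with the control subtracted as listed were chosen only after the data were seen. No paired analysis was possible because each group had 1 sample, except by state in the common heat stress test. Alternatives on gene lists (no gene names), the pseudocount (none used) and single pools (no values) were not run. The cause of the changes below was not tested unless the setting itself shows it.

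At 1.5-fold, which takes in more rows, 15 of the 16 counts were over 1.5 times the main count: against the control 35 (heat stress), 38 (2 d acclimation), 39 (1 mo acclimation), 53 (deacclimation), 54 (reacclimation), and 40, 37 and 62 for heat stress after 2 d acclimation, 1 mo acclimation and reacclimation. It was 25 for 1 mo against 2 d acclimation, 34 for deacclimation against 1 mo acclimation, 34, 43 and 49 for reacclimation against deacclimation, 1 mo and 2 d acclimation, and 37 and 35 for the heat stress responses after 1 mo acclimation and reacclimation.

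By intensity, 10 of 16 counts moved by over 1.5 times: 23 for heat stress, 40 for 2 d acclimation, 40 for 1 mo acclimation and 45 for deacclimation against control, 17 for 1 mo against 2 d acclimation, 26 for deacclimation against 1 mo acclimation, 38 for reacclimation against 2 d acclimation, 22 for the heat stress response after reacclimation, and 38 and 45 for heat stress after 2 d and 1 mo acclimation against control. Of 51 named row results with intensities above 0, 35 stayed 2-fold in the same direction, 10 were no longer 2-fold and 6 had the opposite sign: for heat stress 755R (-1.32) and R198 (0.74), for 1 mo acclimation 635R (-1.13), for reacclimation R208 (-0.37), for heat stress against its own state after reacclimation R590 (0.35), and against control after reacclimation 755R (-0.46).

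Without the 25% of rows with the lowest intensities, which leaves fewer rows to count, 7 of 16 counts moved: 1 for 1 mo against 2 d acclimation, 8 for deacclimation against 1 mo acclimation, 7 and 14 for reacclimation against deacclimation and 2 d acclimation, 13 and 7 for the heat stress responses after 1 mo acclimation and reacclimation, and 13 for heat stress after 1 mo acclimation against control. Centring kept 15 of 16 counts within 1.5 times, the exception being the heat stress response after 2 d acclimation (20), and 62 of 63 named row results. Without values at the floor the heat stress count was 7, and the other 15 stayed within 1.5 times. With the control subtracted as listed, heat stress gave 22 and 1 mo acclimation 21 rows, and 6 of 8 counts stayed within 1.5 times. For heat stress alone the balance turned to 13 higher and 9 lower. Of 6 named row results on such a control value, A061 after 2 d acclimation (0.35) and R724 after deacclimation (1.41) changed sign.

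The common heat stress test called 2 rows, R609 and A044, and 2 rows under centring, without the 25% of rows with the lowest intensities and without values at the floor. It called 0 by intensity, and between 0 and 4 with each state left out in turn (0 without 2 d acclimation or reacclimation). Under these settings R609 was higher by 2.21 to 3.01 and A044 by 1.60 to 2.08.

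The distances of the reacclimated profile stayed within their intervals under centring, without the rows of largest spread, without the dimmest 25% of rows and without values at the floor. As median absolute differences, which weigh extreme rows less, they were 0.40 to the deacclimated, 0.58 to the 1 mo acclimated, 0.65 to the 2 d acclimated and 0.86 to the control profile. The similarities of the 6 pairs of heat stress responses stayed within their intervals under every setting run, though no acclimation with 2 d acclimation was 0.131 and 0.127, and with 1 mo acclimation -0.0958 and -0.0581, without the rows of largest spread and without values at the floor. The count of rows in all 3 groups with an acclimation history was 36 at 1.5-fold and 24 in the second table, and between 13 and 22 under the other settings. Signals near the background limit dim rows (22 in the lowest 25%).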

Other observations

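The intensities of R609 were higher in the heat-stressed than in the unstressed group in all 4 states: 1282 in the control and 27376 after heat stress, 9032 and 35528 for 2 d acclimation, 4073 and 26384 for 1 mo acclimation, and 6439 and 20776 for reacclimation. A022 stood at 11123 after heat stress in 1 mo acclimated rats, 11763 in deacclimated rats, 13606 in reacclimated rats and 14402 in reacclimated rats with heat stress. In the control and in the heat-stressed, 2 d acclimated, 2 d acclimated with heat stress and 1 mo acclimated groups it stood between 1458 and 2492.

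The intensity table repeats some values exactly. The value 3564.3 occurs in 4 rows of the deacclimated group, -645.3 in 3 rows of the reacclimated group, and 166.0 in 2 rows of the reacclimated group with heat stress. Intensities at or below 0 numbered 14 in the 2 d acclimated group with heat stress, 10 in the 2 d acclimated, 6 in the reacclimated and 5 in the deacclimated group.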
